A study of Mus musculus with 60 samples.

How the data were processed

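RNA of 3 brain regions (hippocampus, prefrontal cortex and striatum) was sequenced from mice that lack the adhesion G protein-coupled receptor gene Adgrl3 (KO; the protein is also called latrophilin-3) and from wild-type mice (WT). There were 10 libraries per genotype and region, 60 in all. Per the labels' protocols, 12 mice of each genotype were killed between postnatal days 65 and 76, and the brains were frozen before the regions were dissected by hand. Sex, litter, sequencing batch and the part of Adgrl3 that was altered are not given in the sources used here.

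The deposited table holds raw read counts, as whole numbers, for 21950 protein-coding genes in each of the 60 libraries. Per the submitters' processing notes, FastQC 0.11.4, cutadapt 1.16, STAR 2.5.2b, bedtools, DESeq2 1.16.1 and the mouse build GRCm38 were used, without a role or an order being given. Per the file headers, each feature is a whole gene from start to end, so reads in introns count as well. How the authors' count treated strand is not given in the sources used here and was read from pairs of genes of which one lies inside the other. Among 485 such pairs on the same strand, with at least 6000 reads in the inner gene, 0 had fewer reads in the outer gene. Among 222 pairs on opposite strands 82 did. Reads were thus counted by strand and once for each gene they overlap, and genes that overlap on the same strand share reads. Of the 21950 genes, 265 had no read in any library, and 23 gene symbols stood on more than 1 feature and were kept apart by their identifiers.

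Library totals ran from 38985577 to 51387833 counted reads. Mitochondrial transcripts took 6.94% ± 0.73 (SD, n = 60 libraries) of the counts, and the 10 most abundant genes of a library 7.12% ± 0.66. Replicate libraries were compared pairwise within each group by a chi-square test of their counts over genes with a mean count of at least 20. The statistic per degree of freedom lay between 5.51 and 91.6 over the 45 pairs of each of the groups, so no library had been entered more than once.

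The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, the filterByExpr filter on low counts, robust dispersion estimates and a Benjamini-Hochberg threshold of 0.05. KO and WT were compared within each region on its 20 libraries, with genotype as the sole term. They were also compared over all 60 libraries with region as a second term, which is the combined comparison. Whether the genotype difference itself differed between regions was tested with the 2 interaction terms together, and the regions were compared with each other at the same threshold plus an absolute log2 fold change of at least 1. Levels are in CPM (counts scaled to a common library size) after TMM scaling. Differences are KO minus WT on the log2 scale with their standard errors (SE). The level of Adgrl3 was also compared per region by a two-sided permutation test with 100000 resamples.

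A total of 40 gene lists (synaptic, signalling and stress pathways, cell types, and tissues that lie beside the dissected regions) were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. Benjamini-Hochberg adjustment ran over the 40 lists of a comparison. Each list test was repeated with a correlation estimated from the data and with the fry rotation test. Calls on chromosome 5 were set against the other tested genes by a two-sided Fisher's exact test within 10 Mb of Adgrl3, with Adgrl3 left out. Gene positions are those of the count table (GRCm38).

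The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Adgrl3 in every comparison, the 10 higher and 10 lower genes of smallest p among those that passed, up to 4 members per list that passed over all genes or over the list alone, at most 2 members of smallest p, as values, for a list with none, the interaction genes that passed, and up to 4 members per list for the region contrasts. Genes named outside it were chosen after their values were seen. These are Srd5a3 in hippocampus, the 4 genes of an olfactory bulb score (Eomes, Doc2g, Cdhr1 and Tbx21), and the genes that passed on counts summed per animal and are not named by the rule. Some single-gene results are not reported here.

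Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a filter of 1 CPM in at least 10 libraries, limma voom with quality weights, surrogate variables (sva 3.50.0), all 60 libraries in a single fit, leaving out each animal in turn, and the replicate number as a block. Added after the data were seen were the mean log2 CPM of the 4 olfactory bulb genes as a covariate, summed counts without WT replicate 5, list tests on summed counts, leaving out each animal in turn for the interaction and the whole of chromosome 5 as a window.

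The replicate numbers of the labels run from 1 to 10 in each region and genotype. Whether equal numbers in different regions mark the same animal was checked with the 50 genes of widest gap between animals in the third region. Over the 3 pairs of regions, the deviations of equally numbered libraries of a genotype correlated with r from 0.72 to 0.98, and 18, 20 and 20 of the 20 animals correlated best with their own number, so libraries of equal number and genotype were treated as 1 animal. Over all tested genes the correlation was weaker: hippocampus against striatum had r from -0.19 to 0.44, with 9 of 20 animals correlating best with their own number, where the other 2 pairs of regions had 18 and 19 of 20. This pairing comes from the data and the numbers, and no label states it. The combined comparison counts the 3 libraries of an animal as independent, and its value is therefore printed beside a fit with the animal as a random effect (limma voom with duplicateCorrelation) and a fit of counts summed per animal.

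The main test (apart from 2 of the region contrasts), DESeq2 and voom for KO against WT, and the random-animal, summed and surrogate variable fits of the combined comparison were tested on simulated counts drawn from the means and library sizes of the real genes, with a seeded set of changed genes at log2 differences of 0.3, 0.5 and 1. For the hippocampus comparison (15609 genes), edgeR recovered 62.5%, 87.7% and 96.9% of the genes changed by these sizes. For prefrontal cortex (15352 genes) it recovered 69.8%, 87.5% and 100% and for striatum (15552 genes) 47.6%, 82.8% and 93.8%. For the combined comparison (16088 genes) the shares were 86.6%, 92.5% and 97.0%, and on counts summed per animal (16119 genes) 79.1%, 91.0% and 95.5%. For the interaction (16081 genes) they were 40.3%, 71.2% and 89.2%, and for striatum against hippocampus (15889 genes) 65.7%, 84.6% and 98.5%. False calls of edgeR made up 5.88%, 4.68%, 3.36% and 6.60% of the calls in the 3 regions and the combined comparison, and those of DESeq2 12.2%, 11.7%, 15.4% and 9.41%. The simulated libraries were independent and held no variation shared by the libraries of 1 animal. The shares of the fits over all 60 libraries, false calls included, may therefore not hold in the real data.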

Results

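Gene expression was measured by RNA sequencing in hippocampus, prefrontal cortex and striatum of Adgrl3 knockout (KO) and wild-type (WT) mice killed at 65 to 76 days of age. Adgrl3 encodes latrophilin-3, an adhesion G protein-coupled receptor of neurons in which human variants have been associated with attention deficit hyperactivity disorder (ADHD). Each region was represented by 10 KO and 10 WT libraries, and each library held between 38985577 and 51387833 counted reads. The design asked which genes differ between the genotypes in each region taken alone, and which differ when the 3 regions are combined. Equally numbered libraries of a genotype were treated as 1 animal after a check of their values, which no label states. The 60 libraries are thus taken to come from 20 animals.

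Adgrl3 (ENSMUSG00000037605.16; GRCm38 chromosome 5, 81020138 to 81825133, plus strand) was lower in each of the KO libraries than in each of the WT libraries of its region. In the hippocampus its level was 34.9 ± 3.07 CPM in KO and 125.2 ± 5.33 CPM in WT (SD, n = 10 each). In prefrontal cortex the levels were 35.2 ± 8.93 and 149 ± 16.1 CPM, and in striatum 41.8 ± 5.26 and 163 ± 9.42 CPM. KO animals thus kept 27.9%, 23.6% and 25.6% of the WT level, counted over the whole gene including introns, which does not show which part of the gene these reads came from. On the log2 scale Adgrl3 fell by 1.84 ± 0.04, 2.09 ± 0.13 and 1.96 ± 0.06 (SE) in hippocampus, prefrontal cortex and striatum, with Benjamini-Hochberg adjusted p of 2.54e-18, 6.30e-09 and 9.60e-16 (edgeR quasi-likelihood). A two-sided permutation test gave p = 1e-05 in each region, the smallest that 100000 resamples can give.

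**Figure D1:**
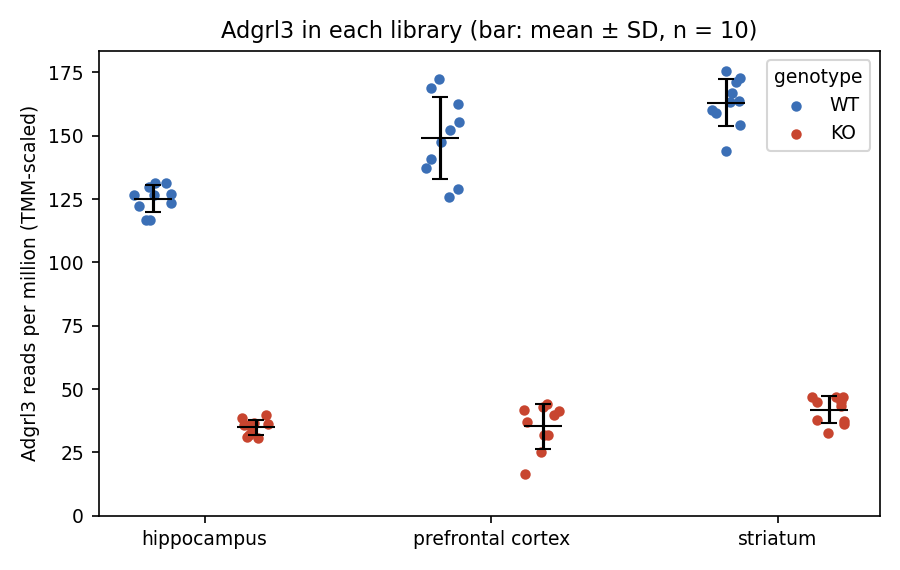
Level of Adgrl3 in each library, in TMM-scaled CPM, by region and genotype (points are libraries, bars the mean ± SD of 10). The highest KO library of a region reached 39.6, 44.2 and 47.0 CPM in hippocampus, prefrontal cortex and striatum, and the lowest WT library 117, 126 and 144 CPM.

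In the hippocampus, Stbd1, which encodes a glycogen-binding protein, rose from 2.07 ± 2.06 CPM in WT to 7.28 ± 1.26 CPM in KO (SD, n = 10 each), a log2 difference of 1.81 ± 0.31 (SE). Cox18, whose product inserts a cytochrome oxidase subunit into the mitochondrial inner membrane, rose from 9.89 ± 1.504 to 16.6 ± 0.999 CPM, by 0.74 ± 0.07. Hspb8, a small heat shock protein gene, fell by 0.94 ± 0.17, Idua, the gene of a lysosomal enzyme, fell by 0.73 ± 0.13, and Naaa, which encodes an enzyme that breaks down N-acylethanolamines, fell by 0.54 ± 0.06. Smaller changes were found for the actin regulators Ssh1 (0.37 ± 0.06) and Coro1c (-0.31 ± 0.05), the kinase gene Cdkl2 (0.31 ± 0.04), the ribosomal stalk protein gene Rplp0 (-0.32 ± 0.05) and Gcn1l1 (0.23 ± 0.04), whose product activates a translation-regulating kinase.

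Over all genes, 20 of 15581 passed the test in the hippocampus, 9 higher and 11 lower in KO (edgeR quasi-likelihood, Benjamini-Hochberg). For each of the 20, the 10 KO libraries lay on 1 side of the WT mean. On chromosome 5 lay 18 of the 20. The others were the keratin gene Krt73 (0.38 ± 0.08, chromosome 15) and the kinase gene Rps6kc1 (0.11 ± 0.02, chromosome 1), at adjusted p = 0.0417 each. The remaining genes that rose, Mthfd2l (0.30 ± 0.06) and Ociad1 (0.14 ± 0.03), and those that fell, Anxa3 (-0.41 ± 0.08), Sdad1 (-0.30 ± 0.04), Adamts3 (-0.27 ± 0.04), Paqr3 (-0.25 ± 0.04) and Srd5a3 (-0.22 ± 0.04), were on chromosome 5 as well. DESeq2 called 47 genes in the same libraries, 28 of them on chromosome 5.

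Erythrocyte markers were lower in KO hippocampus. Of 6 measured, 0 passed over all genes and 5 fell adjusted over the list alone, among them the globin genes Hbb-bs (-0.57 ± 0.17), Hbb-bt (-0.56 ± 0.17) and Hba-a2 (-0.56 ± 0.18) and the haem synthesis gene Alas2 (-0.63 ± 0.20). The list test gave adjusted p = 6.79e-07 (camera), and adjusted p = 0.55 with an estimated correlation. The 15 choroid plexus markers had a median log2 difference of -0.61 (camera adjusted p = 1.08e-04) and the 12 ependymal markers one of -0.23 (0.0261), with adjusted p = 0.863 with an estimated correlation for both. Oligodendrocyte markers (median -0.13, adjusted p = 0.0168) and ribosomal protein genes (median -0.02, adjusted p = 0.0261) were shifted down by camera, and the 24 heat shock and endoplasmic reticulum stress genes up (median 0.07, adjusted p = 1.49e-04). Each of these 3 had adjusted p = 0.863 with an estimated correlation. None of their members passed over all genes in the edgeR test, which had 1269 genes at an unadjusted p under 0.05, where DESeq2 had 1341. Adjusted over the list alone, Rpl5 (-0.10 ± 0.03), Plin4 of the glucocorticoid-responsive list (-1.12 ± 0.28) and Adgrf5 (-0.18 ± 0.05) fell, and Clock (0.10 ± 0.02), Gpr17 (0.24 ± 0.06) and Nos1 of the ADHD list (0.22 ± 0.05) rose. Rpl5, Clock and Nos1 lie on chromosome 5.

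In prefrontal cortex the same chromosome 5 genes led the list. Stbd1 rose from 2.53 ± 2.86 to 9.90 ± 1.68 CPM (SD, n = 10 each; log2 difference 1.97 ± 0.35, SE), and by 2.59 ± 0.14 without WT replicate 5, which had 10.6 CPM where the other WT libraries had 0.937 to 2.38. Cox18 rose by 0.76 ± 0.05, Idua fell by 0.74 ± 0.10 and Naaa fell by 0.54 ± 0.07. Prdm8 (0.39 ± 0.06), which encodes a transcriptional repressor, the lysosomal membrane protein gene Scarb2 (0.29 ± 0.05) and the synaptic vesicle gene Rph3a (0.17 ± 0.03) rose, and the extracellular matrix gene Fras1 (-0.41 ± 0.08) fell. Off chromosome 5, the epidermal filaggrin gene Flg rose from 7.92 ± 1.18 to 10.9 ± 0.94 CPM (0.46 ± 0.07, edgeR adjusted p = 0.00504). Tmem151b (0.30 ± 0.06, adjusted p = 0.0411) and Hr, a nuclear corepressor gene (0.29 ± 0.06, adjusted p = 0.0497), rose by less. Scgn, which encodes a calcium-binding protein abundant in olfactory bulb interneurons, fell by 2.20 ± 0.44, from 1.24 ± 0.74 to 0.26 ± 0.22 CPM (edgeR adjusted p = 0.0497).

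In total 18 of 15376 genes passed in prefrontal cortex, 10 higher and 8 lower in KO and 14 of them on chromosome 5 (edgeR quasi-likelihood, Benjamini-Hochberg), with the 10 KO libraries on 1 side of the WT mean for each. The genes not named above were Cdkl2 (0.28 ± 0.04), Gcn1l1 (0.29 ± 0.05), Sdad1 (-0.33 ± 0.05), Coro1c (-0.27 ± 0.05) and Rplp0 (-0.28 ± 0.06). The count depended on the tool and the samples behind the fit: DESeq2 called 214 genes, 173 of them off chromosome 5, voom with quality weights 55, edgeR with surrogate variables 4 and edgeR on all 60 libraries in a single fit 208.

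Markers of the olfactory bulb and of newborn neurons, tissue that lies in front of the prefrontal cortex, were lower in KO prefrontal cortex. Of 10 measured, 0 passed over all genes and 9 fell adjusted over the list alone, with a median of -1.29 (camera adjusted p = 2.01e-11, adjusted p = 0.0896 with an estimated correlation). The transcription factor genes Tbx21 and Sp8 differed by -1.72 ± 0.44 and -0.998 ± 0.28, and Doc2g by -1.86 ± 0.52. Th, the rate-limiting enzyme of dopamine synthesis, differed by -1.58 ± 0.36 (7.99 ± 3.94 CPM in WT and 2.66 ± 1.75 in KO), and Slc6a3, the dopamine transporter gene, by -2.99 ± 0.75. Of the 19 measured dopamine genes, 0 passed over all genes, Th and Slc6a3 fell and Ppp1r1b rose (0.26 ± 0.08) adjusted over the list alone. The size of the Slc6a3 difference depended on WT replicate 5, which had 8.74 CPM where the other WT libraries had 0.0992 to 1.08 CPM, and without that library it was -1.70 ± 0.37. With the mean log2 CPM of Eomes, Doc2g, Cdhr1 and Tbx21 taken as an olfactory bulb score, WT libraries scored 2.35 ± 1.35 and KO libraries 0.22 ± 1.32 (SD, n = 10 each). With this score as a covariate, chosen after the data were seen, 6 genes passed, 5 of them on chromosome 5, and Th differed by -0.30 ± 0.16 and Scgn by -0.57 ± 0.22. Other genes lost their call at a similar difference with a larger SE, among them Stbd1 (2.01 ± 0.46), Cdkl2 (0.28 ± 0.06), Flg (0.45 ± 0.10), Tmem151b (0.29 ± 0.08) and Hr (0.30 ± 0.08).

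**Figure D2:**
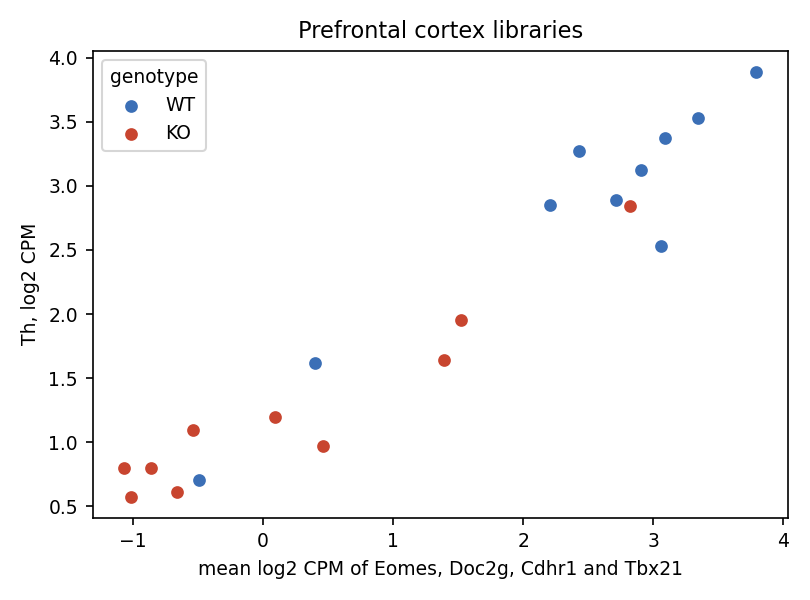
Th (log2 CPM, vertical axis) against the mean log2 CPM of 4 olfactory bulb genes (horizontal axis) in the 20 prefrontal cortex libraries, coloured by genotype. Scores ran from -0.49 to 3.79 in WT and from -1.07 to 2.82 in KO, and libraries of both genotypes followed a common trend.

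Other lists differed in prefrontal cortex, in part together with this score. The 16 hypothalamus, septum and pituitary markers had 10 measured members, of which 4 fell adjusted over the list alone, among them the thyrotropin-releasing hormone gene Trh (-1.89 ± 0.38) and Zic1 (-0.50 ± 0.18; camera adjusted p = 0.00569, adjusted p = 0.248 with an estimated correlation). GABA genes were shifted down (camera adjusted p = 0.0468, adjusted p = 0.806 with an estimated correlation), with Gad1 (-0.18 ± 0.05) and Gabra5 (-0.16 ± 0.04) past the threshold adjusted over the list alone. Of 17 excitatory neuron markers 4 rose adjusted over the list alone, among them Neurod2 (0.20 ± 0.07), Nptx1 (0.23 ± 0.07) and Neurod6 (0.16 ± 0.06), with camera adjusted p = 0.00356 and adjusted p = 0.0896 with an estimated correlation. Oligodendrocyte markers were higher, with 8 of 15 up adjusted over the list alone, among them Fa2h (0.36 ± 0.10) and Mog (0.25 ± 0.09; camera adjusted p = 6.81e-09, adjusted p = 0.472 with an estimated correlation). Erythrocyte markers were lower as in hippocampus, with 5 of 6 down adjusted over the list alone and Alas2 at -0.71 ± 0.17 (camera adjusted p = 1.92e-08, adjusted p = 0.173 with an estimated correlation). Microglia markers were shifted up, with Tmem119 (0.19 ± 0.05) and Selplg (0.16 ± 0.05) past the threshold adjusted over the list alone (camera adjusted p = 0.00253, adjusted p = 0.506 with an estimated correlation). Tmem119 and Selplg both lie on chromosome 5, next to the called gene Coro1c. Immediate early genes and heat shock genes were shifted up (medians 0.18 and 0.09, camera adjusted p = 0.00253 and 5.75e-04) and mural and meningeal markers down (median -0.23, adjusted p = 0.00213), each with adjusted p = 0.806 with an estimated correlation. With the olfactory bulb score as a covariate camera kept the calls of the erythrocyte (adjusted p = 8.60e-04), heat shock (0.0019), oligodendrocyte (0.0198) and excitatory neuron lists (0.0421). The olfactory bulb list holds the 4 genes of the score and cannot be judged with it. Camera no longer called the hypothalamus (0.198), GABA (0.773), microglia (0.378), immediate early (0.194) and mural lists (0.0788), and it called glutamate genes (up, 0.00931), serotonin and noradrenaline genes (up, 0.0187), potassium and sodium channels (up, 0.0362) and hippocampal neuron markers (down, 0.0499). Over all genes 0 members of these lists passed in edgeR's test without the score, which had 1808 genes at an unadjusted p under 0.05, where DESeq2 had 1895.

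Single members of further lists passed adjusted over the list alone in prefrontal cortex. The interneuron genes Calb2 (-0.95 ± 0.22) and Npy (0.26 ± 0.07), the adrenergic receptor genes Adra1b (0.15 ± 0.04) and Adra1d (0.21 ± 0.06), and the serotonin receptor genes Htr1a (-0.24 ± 0.08) and Htr1d (-0.58 ± 0.20) were among them. So were the axon guidance genes Ephb2 (0.16 ± 0.04), Nrp1 (0.29 ± 0.08) and Sema4d (0.16 ± 0.05), the somatostatin receptor gene Sstr2 (0.35 ± 0.10), the vesicle release gene Cplx2 (0.11 ± 0.03), the endothelial gene Emcn (0.28 ± 0.07) and the water channel gene Aqp1 of the choroid plexus list (-1.54 ± 0.38).

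In striatum, Stbd1 rose from 0.86 ± 0.51 to 3.02 ± 0.62 CPM (SD, n = 10 each; log2 difference 1.80 ± 0.21, SE) and Cox18 from 8.69 ± 0.85 to 13.8 ± 0.85 CPM (0.66 ± 0.05). Gcn1l1 rose by 0.33 ± 0.06. Shroom3, which encodes an actin-binding protein of epithelia, fell by 1.09 ± 0.20, from 4.03 ± 0.98 to 1.89 ± 0.84 CPM, the DNA repair gene Brca2 fell by 0.44 ± 0.08, Naaa fell by 0.36 ± 0.06 and Sdad1 fell by 0.32 ± 0.05. With Adgrl3 these were the genes that passed, 8 of 15553, 3 higher and 5 lower in KO, with the 10 KO libraries on 1 side of the WT mean (edgeR quasi-likelihood, Benjamini-Hochberg). On chromosome 5 lay 8 of the 8, and 0 genes off it passed in edgeR's test, which had 1110 genes at an unadjusted p under 0.05. DESeq2 called 25 genes, surrogate variables gave 17, and the fit of all 60 libraries 22. Leaving out WT replicate 5 gave 15.

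Camera shifted 12 lists in striatum. Of 24 heat shock and endoplasmic reticulum stress genes 5 were up adjusted over the list alone, among them Xbp1 (0.32 ± 0.10), Pdia4 (0.34 ± 0.10), Chordc1 (0.27 ± 0.08) and Sdf2l1 (0.52 ± 0.16; camera adjusted p = 1.00e-05 for the list). KO replicates 4, 8 and 10 had the highest mean of this list among the 20 libraries (6.58, 6.70 and 6.71). Shifted up as well were the lists of ribosomal protein genes (adjusted p = 0.00109), nuclear respiratory chain genes (0.00215), oligodendrocyte markers (0.00291), immediate early genes (0.00482), cholinergic markers (0.0154), microglia markers (0.0168) and mitochondrially encoded transcripts (0.0214), by medians from 0.04 to 0.15. Shifted down were presynaptic vesicle genes (camera adjusted p = 0.00169, median -0.06), erythrocyte markers (0.00169, median -0.31), the latrophilins without Adgrl3 and their binding partners (0.0158, median -0.06) and neuronal cell adhesion genes (0.0437, median -0.04). Each of the 12 had adjusted p = 0.708 with an estimated correlation. KO replicates 8, 9 and 10 had the lowest mean log2 CPM of the 20 libraries for the vesicle, cell adhesion and latrophilin partner lists (6.30, 6.26 and 6.21 for the last). Per animal over the 3 regions the latrophilin partner and cell adhesion lists differed by -0.02 each (permutation p = 0.596 and 0.601, adjusted p = 0.858 by Benjamini-Hochberg for both). Over all genes 0 members of any list passed in striatum in edgeR's test. Adjusted over the list alone, the vesicular monoamine transporter gene Slc18a2 (0.69 ± 0.19), Gpr17 (0.23 ± 0.07) and the vasopressin gene Avp (3.20 ± 0.79) rose and Pdgfra (-0.13 ± 0.04), a chromosome 5 gene, fell. Avp had 0.30 ± 0.12 CPM in WT and 2.80 ± 3.94 in KO (SD, n = 10 each), and KO replicates 2, 9 and 10 had the highest mean over the hypothalamus list of the 20 libraries (3.91, 3.91 and 4.16), which leaves neighbouring tissue in these samples open. The genes of smallest p among the latrophilin partners were Tenm4 (-0.17 ± 0.08) and Unc5d (-0.28 ± 0.13), neither of which passed.

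The genes called in each of the 3 regions were Adgrl3, Cox18, Naaa, Sdad1, Stbd1 and Gcn1l1, 6 in all. Another 4, Cdkl2, Coro1c, Idua and Rplp0, were called in 2 regions and 20 in 1. Of the 30 genes called in any region 24 lay on chromosome 5. Within 10 Mb of Adgrl3, 5 of 64 tested genes were called in hippocampus against 14 of 15516 elsewhere (Fisher's exact p = 1.11e-08, odds ratio 93.2 with a 95% interval from 25.5 to 284). In prefrontal cortex it was 1 of 61 (p = 0.0654) and in striatum 1 of 66 (p = 0.0293). Over the whole of chromosome 5, a window chosen after the data were seen, 17 of 948 genes were called in hippocampus, 13 of 932 in prefrontal cortex and 7 of 946 in striatum, Adgrl3 left out (p = 2.86e-19, 2.61e-13 and 3.02e-09). Called genes spanned 43.1 Mb of the chromosome in hippocampus (73292784 to 116422864), 40.0 Mb in prefrontal cortex (81020138 to 121010092) and 69.6 Mb in striatum (81020138 to 150570329). The far end in striatum was set by Brca2 alone (edgeR adjusted p = 0.0489), and the next called gene there, Gcn1l1, ended at 115622654.

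**Figure D3:**
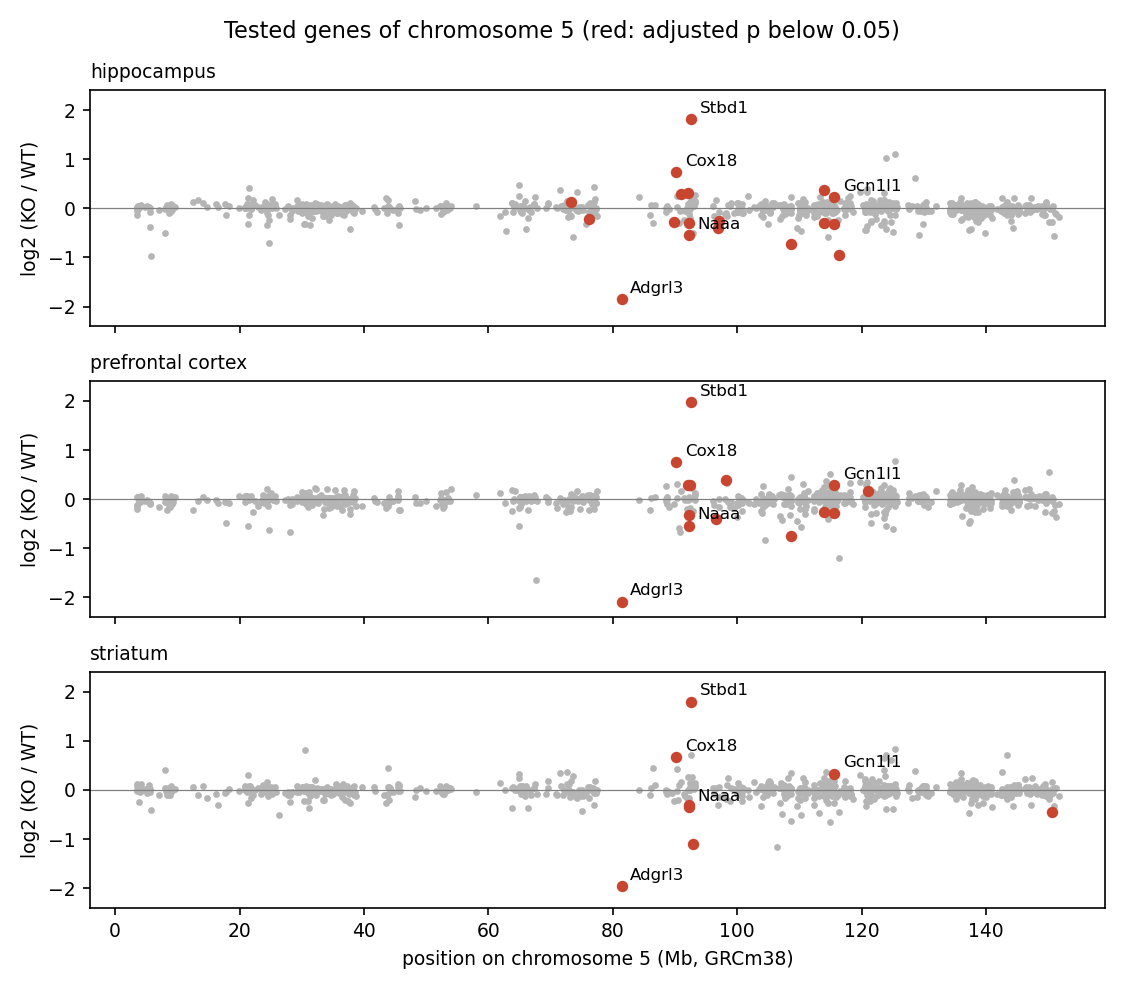
Log2 difference (KO over WT, vertical axis) of the tested genes along chromosome 5 (horizontal axis, Mb of GRCm38) in each region, with genes at adjusted p under 0.05 in red. Called genes lay on both sides of Adgrl3 in hippocampus and at higher positions in the other regions, and Adgrl3, Stbd1, Cox18, Naaa and Gcn1l1 are labelled.

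The 23 called chromosome 5 genes other than Adgrl3 did not split cleanly by genotype. Each animal was placed by its log2 CPM, on counts summed over the regions, on a scale from 0, the mean of the WT animals, to 1, the mean of the KO animals. The animal being placed was left out of these means. For Fras1 and Prdm8 the genotypes hardly differed on summed counts, so their values ran far off the scale (Fras1 -178 in KO replicate 1, Prdm8 -88.9 in WT replicate 7). Both stay in the counts and medians below. WT replicate 5 lay at a median of 0.917 over the 23 genes, with 17 of them past the midpoint, while its Adgrl3 level of 144 CPM was that of a WT animal. Its called genes within 10 Mb of Adgrl3 lay lower, from -0.18 (Ociad1) to 0.51 (Cox18). So did Rph3a (0.17) and Brca2 (-0.29), the farthest from Adgrl3. The other WT animals had medians between -0.29 and -0.04. KO replicates 5, 7 and 8 lay at 1.03, 0.870 and 1.01 over the 15 genes from Ociad1 to Prdm8 and at 0.598, 0.521 and 0.495 over the 8 genes from Idua to Brca2.

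**Figure D4:**
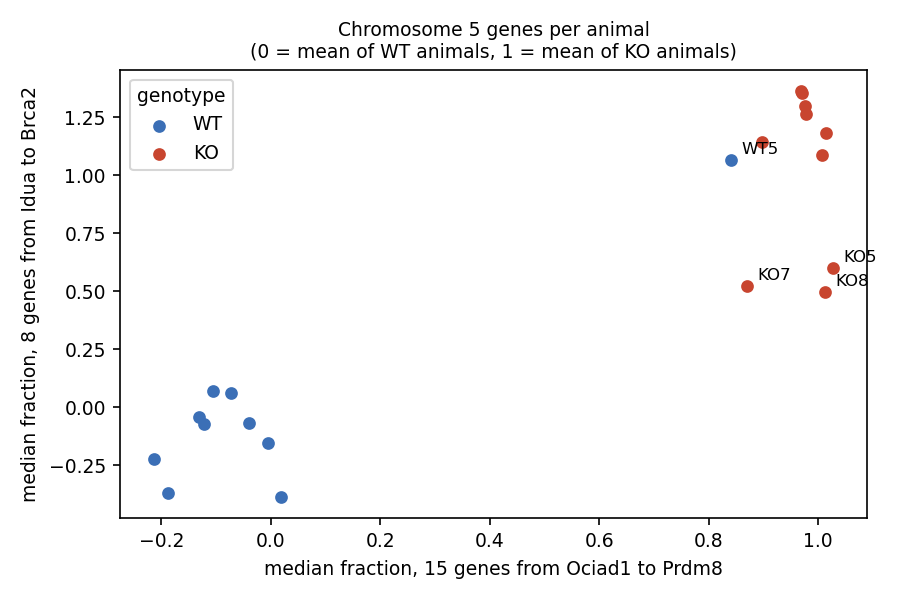
Position of each animal between the WT mean (0) and the KO mean (1), as the median over 8 called genes of chromosome 5 from Idua to Brca2 (vertical axis) and over 15 called genes from Ociad1 to Prdm8 (horizontal axis). WT replicate 5 lies just below the KO animals on the horizontal axis (0.842, lowest KO animal 0.870) and among them on the vertical axis (1.06). KO replicates 5, 7 and 8 lie near the middle of the vertical axis.

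Combined over the 3 regions, the same chromosome 5 genes were among those of smallest p: Adgrl3 fell by 1.96 ± 0.05 (SE), Stbd1 rose by 1.87 ± 0.18, Cox18 rose by 0.72 ± 0.03, Hspb8 fell by 0.86 ± 0.12, Idua fell by 0.70 ± 0.07 and Naaa fell by 0.48 ± 0.04 (30 libraries per genotype from 10 animals each). Off chromosome 5, Flg rose by 0.36 ± 0.05, from 9.04 ± 1.72 to 11.6 ± 1.43 CPM (SD), with 30 of 30 KO libraries above the WT mean over the 3 regions. Dio2, which encodes the deiodinase that activates thyroid hormone, rose by 0.32 ± 0.05, with 22 of 30 above that mean. Counts against a mean over the regions also reflect differences between regions. The remaining leading genes lay on chromosome 5 too. Cdkl2 (0.29 ± 0.03), Ssh1 (0.29 ± 0.04), Gcn1l1 (0.29 ± 0.03), Scarb2 (0.19 ± 0.03), Ccng2 (0.18 ± 0.03) and Ociad1 (0.14 ± 0.02) rose. Anxa3 (-0.36 ± 0.05), Sdad1 (-0.31 ± 0.03), Rplp0 (-0.28 ± 0.03), Coro1c (-0.23 ± 0.03), Srd5a3 (-0.20 ± 0.02) and Paqr3 (-0.19 ± 0.03) fell.

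In the combined comparison 650 of 16121 genes passed (edgeR quasi-likelihood, Benjamini-Hochberg), 364 higher and 286 lower in KO. Most changes were small, with a median absolute log2 difference of 0.12 and 31 genes at 0.5 or more. On chromosome 5 lay 111 of the 650, and 81 of these lay in the part of the chromosome from 70 Mb to just past the last gene called in prefrontal cortex. This test counts the 3 libraries of an animal as independent: with the animal as a random effect 187 genes passed, 184 of them among the 650, and on counts summed per animal 27 passed, all 27 among the 650 and 23 of them on chromosome 5. Off chromosome 5 the summed counts called Flg (0.35 ± 0.06, adjusted p = 0.00967), the amino acid transporter gene Slc1a5 (-0.36 ± 0.06, 0.0127), the synaptic adhesion gene Lrrtm2 (0.14 ± 0.03, 0.0497) and the photoreceptor gene Fscn2 (-0.59 ± 0.12, 0.0497), while Dio2 (adjusted p = 0.052), Ssh1 (0.0767) and Anxa3 (0.0814) no longer passed in edgeR. Leaving out 1 animal at a time moved the 650 most for KO replicates 5 (1133), 1 (1076), 8 (308), 9 (392) and 10 (399).

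Some genes of the stress response rose in the combined comparison. Of 24 heat shock and endoplasmic reticulum stress genes 5 rose over all genes and 10 adjusted over the list alone. These included Xbp1, a transcription factor of the unfolded protein response (0.28 ± 0.06), the disulfide isomerase gene Pdia4 (0.26 ± 0.06), Creld2 (0.28 ± 0.07) and the chaperone gene Chordc1 (0.19 ± 0.04). The list test gave adjusted p = 3.13e-07 (camera) and adjusted p = 0.994 with an estimated correlation. On counts summed per animal the edgeR adjusted p of these 4 genes was 0.316, 0.330, 0.361 and 0.266, and the mean of the list per animal differed by 0.10 (permutation p = 0.161, adjusted p = 0.754 by Benjamini-Hochberg). KO replicates 4, 8 and 10 had the 3 highest means of the list in each region (6.68, 6.75 and 6.72 in hippocampus, 6.80, 6.87 and 6.97 in prefrontal cortex). Per animal, 7 of the 10 KO animals lay above the WT mean of the list. Whether the KO animals other than these 3 rose was not tested. Of 24 immediate early genes Inhba, an activin subunit gene, rose (0.45 ± 0.11, adjusted p = 0.322 on summed counts; camera adjusted p = 0.00186 for the list, adjusted p = 0.994 with an estimated correlation).

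Most erythrocyte markers fell. Of 7 measured 5 fell over all genes, Hbb-bs (-0.49 ± 0.09), Hbb-bt (-0.48 ± 0.09), Hba-a2 (-0.48 ± 0.10) and Alas2 (-0.57 ± 0.11) among them, and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 1.78e-06, adjusted p = 0.412 with an estimated correlation). The list's median was -0.48 and its mean 0.02, which differ in sign, and the mean of its members per animal was 0.28 higher in KO (permutation p = 0.393, adjusted p = 0.858 by Benjamini-Hochberg). On summed counts the 4 named genes had adjusted p from 0.164 to 0.220 in edgeR. Of the 11 olfactory bulb markers 2 fell over all genes and 5 adjusted over the list alone, Tbx21 (-1.08 ± 0.27) and Th (-0.59 ± 0.18) among them (camera adjusted p = 0.0018, adjusted p = 0.994 with an estimated correlation; adjusted p = 0.125 and 0.0833 for the 2 genes on summed counts). With the olfactory bulb score as a covariate 364 genes passed.

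Microglia markers were higher. Of 14, 3 rose over all genes and 6 adjusted over the list alone, with Tmem119 at 0.16 ± 0.03, the fractalkine receptor gene Cx3cr1 at 0.07 ± 0.02 and Selplg at 0.10 ± 0.03 (camera adjusted p = 0.0018, adjusted p = 0.994 with an estimated correlation). On summed counts their edgeR adjusted p was 0.163, 0.224 and 0.320. Tmem119 and Selplg lie on chromosome 5, at 113793729 to 113800516 and 113818536 to 113832644, next to the called gene Coro1c, and the span of Cx3cr1 overlaps other genes on its strand, so its count includes their reads. Mural and meningeal markers were shifted down (median -0.10, camera adjusted p = 0.015) and nuclear respiratory chain genes (median 0.02, 0.0182) and mitochondrially encoded transcripts (median 0.04, 0.03) up, with adjusted p = 0.994 with an estimated correlation for each and 0 members past the threshold over all genes in edgeR. With an estimated correlation 0 of the list calls of any comparison held, and by fry 4 lists passed in prefrontal cortex (olfactory bulb and excitatory neuron markers at adjusted p = 0.0183, erythrocyte and hypothalamus markers at 0.0427) and 1 in the combined comparison (erythrocyte markers, 0.00636).

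Single members of other lists passed in the combined comparison. Among synaptic genes the postsynaptic scaffold genes Homer1 (0.34 ± 0.08) and Shank3 (0.08 ± 0.02) rose, 2 of 37 glutamate genes, as did 3 of 54 cell adhesion genes, Lrrtm2 (0.14 ± 0.03), Lrrtm1 (0.12 ± 0.03) and Lrfn2 (0.22 ± 0.06). Gpr17, a receptor of differentiating oligodendrocyte precursors, rose by 0.23 ± 0.04, 1 of 8 precursor markers. The axon guidance gene Ephb2 (0.16 ± 0.03), the calcium channel gene Cacnb1 (0.10 ± 0.03), the circadian gene Clock (0.08 ± 0.02), the endothelial gene Emcn (0.18 ± 0.04), St3gal3 of the ADHD list (0.06 ± 0.02) and the melanin-concentrating hormone gene Pmch of the hypothalamus list (2.85 ± 0.66) rose. For Pmch 16 of 30 KO libraries lay above the WT mean over the 3 regions (3.12 ± 10.7 CPM in KO, SD), so a few libraries carried the difference and neighbouring tissue stays open as for Avp. Abcb1a (-0.10 ± 0.03), Adgrf5 (-0.12 ± 0.03), Rpl5 (-0.07 ± 0.02) and the lipid droplet gene Plin4 of the glucocorticoid-responsive list (-1.06 ± 0.24) fell. Of these, Clock, Abcb1a and Rpl5 lie on chromosome 5. On counts summed per animal Lrrtm2 had adjusted p = 0.0497 in edgeR, Emcn 0.0748, Gpr17 0.148 and Homer1 0.320, and of the genes in this paragraph Lrrtm2 was the one that passed.

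The other lists had no camera call in the combined comparison. On counts summed per animal, a test added after the data were seen, camera called 3 of them, choroid plexus markers (down, adjusted p = 6.60e-04), cholinergic markers (up, 0.00540) and oligodendrocyte markers (up, 0.0105), beside the 8 called above. For the mean of these 3 lists per animal no difference passed (permutation p = 0.246, 0.761 and 0.570, adjusted p = 0.820, 0.951 and 0.858 by Benjamini-Hochberg). In the combined comparison camera's adjusted p was 0.0813 for choroid plexus, 0.216 for glucocorticoid-responsive genes, 0.269 for GABA genes, 0.273 for other adhesion G protein-coupled receptors, 0.302 for oligodendrocyte markers, 0.412 for ribosomal proteins, 0.626 each for presynaptic vesicle genes, ependymal markers and sex chromosome genes, and 0.666 for cell adhesion genes. It was 0.703 each for glutamate genes, astrocyte markers and hippocampal neuron markers, 0.72 for the latrophilins and their partners, 0.761 for hypothalamus markers, 0.771 for endothelial markers, 0.775 for serotonin and noradrenaline genes, 0.825 each for potassium and sodium channels and thalamus markers, 0.840 each for oligodendrocyte precursor and cholinergic markers, and 0.848 for neuropeptides. For dopamine, ADHD, calcium channel, axon guidance, clock, growth factor and Wnt, reactive immune, excitatory neuron, interneuron and medium spiny neuron genes it was 0.989. For the calcium channel, axon guidance, growth factor and Wnt, reactive immune, medium spiny neuron and hippocampal lists the median, the mean and the camera direction differed in sign. Of the 21 measured dopamine genes Th alone passed over all genes. Of 18 latrophilins and partners, a list without Adgrl3 itself, 0 did in edgeR, the smallest p being those of Tenm4 (-0.11 ± 0.04) and Cntn6 (-0.13 ± 0.05).

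The genotype difference itself differed between regions for 4 genes (edgeR quasi-likelihood interaction test, Benjamini-Hochberg): Scgn (adjusted p = 0.0235), and Slc6a3, Nmb and Nudt8 (0.0472 each). All 4 differed in prefrontal cortex, by -2.20 ± 0.44, -2.99 ± 0.75, -1.07 ± 0.27 and -0.999 ± 0.25 (SE), of which Scgn passed there on its own. In hippocampus the same genes differed by 0.11 ± 0.17, -0.17 ± 0.24, 0.06 ± 0.09 and -0.12 ± 0.07, and in striatum by 0.13 ± 0.28, 0.81 ± 0.43, 0.14 ± 0.10 and 0.12 ± 0.06. The striatum value of Slc6a3 rested on KO replicate 10 (2.16 CPM, other KO libraries 0.153 to 0.386) and was 0.08 ± 0.22 without it, and its prefrontal cortex value was -1.70 ± 0.37 without WT replicate 5. The Nudt8 feature (ENSMUSG00000024869.10) overlaps Doc2g on the same strand and Nmb overlaps Sec11a, so they share reads. Th was next, at adjusted p = 0.0545. These genes moved with the olfactory bulb score given above, and with it as a covariate 0 genes passed in edgeR, with 353 at an unadjusted p under 0.05. With the animal as a block 0 genes passed as well, with 1092 at an unadjusted p under 0.05, and DESeq2 called 17.

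The regions were compared to place each library by its tissue. The medium spiny neuron markers were higher in striatum in 20 of 20 measured members, with a median log2 difference of 4.43 against hippocampus and 4.64 against prefrontal cortex. Cholinergic markers were higher in striatum, with Chat, the acetylcholine-synthesising enzyme gene, at 30.6 ± 4.26 CPM against 0.61 ± 0.69 in hippocampus and 0.66 ± 0.18 in prefrontal cortex (SD, n = 20). Hippocampal neuron markers were higher in hippocampus than in prefrontal cortex in 11 of 15 (median 3.45), with the dentate gyrus gene C1ql2 at 68.2 ± 15.1 against 0.91 ± 0.28 CPM. The cortical gene Cux2 stood at 113 ± 10.6 CPM in prefrontal cortex and 28.2 ± 5.37 in hippocampus. All 15 oligodendrocyte markers followed the order striatum, hippocampus, prefrontal cortex, with Cnp at 511 ± 91.5, 226 ± 53.4 and 129 ± 17.4 CPM. Choroid plexus markers were higher in hippocampus and striatum than in prefrontal cortex in 15 of 15, and Ttr varied widely between libraries of a region (1051 ± 962 CPM in hippocampus, 394 ± 351 in striatum and 6.10 ± 11.8 in prefrontal cortex). At an absolute log2 difference of at least 1, 1681 of 16121 genes differed between striatum and hippocampus (888 higher in striatum), 2021 between striatum and prefrontal cortex (1248 higher in striatum) and 1684 between hippocampus and prefrontal cortex (989 higher in hippocampus; edgeR quasi-likelihood, Benjamini-Hochberg).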

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

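Chosen only after the results were seen were the odds ratio over chromosome 5, the count of neighbours within 10 Mb, the count of splits over 100 genes, and the values of Scgn, Slc6a3 and Trh with the olfactory bulb score. The called genes behind both correlations below came from these same data, and the olfactory bulb score was also chosen after the data were seen.

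In the edgeR test of each region most calls lay on chromosome 5. Loss of Adgrl3 acting anywhere in the genome would leave the odds ratio of these calls near 1, and its lowest lower 95% bound over the 3 regions was 15.7, which leaves smaller effects elsewhere open. Of the 23 called chromosome 5 genes other than Adgrl3, 5 lay within 10 Mb of it. An effect of the targeted allele on neighbours at that distance would leave most of the 23 unexplained and stays open for the 5. The count depends on that limit: Cdkl2, Naaa, Sdad1, Scarb2, Stbd1 and Shroom3 lay 10.2 to 10.9 Mb away. For the 15 called genes from Ociad1 to Prdm8, the farthest at 16.3 Mb, such an effect stays open at a wider limit. The 8 called genes from Idua to Brca2 moved together on average within the 10 KO animals (mean pairwise correlation 0.482, 95th percentile of random gene sets 0.164). A piece of another strain's chromosome 5, kept beside the targeted allele and cut short by recombination in some animals, could give such a pattern. On the scale from WT (0) to KO (1), Brca2 lay at 2.23 and Hspb8 at 0.14 in KO replicate 8. In KO replicate 7 Rph3a lay at 1.10 and Hspb8 at 0.28, so the values do not carry this reading past Hspb8. WT replicate 5 had a WT level of Adgrl3. On the same scale its called genes within 10 Mb of Adgrl3 lay between -0.18 and 0.51, and those from Naaa to Hspb8 at 0.82 or more. KO-like levels at such a distance may fit the same reading, but no genotype of the strain was tested here.

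Olfactory bulb markers, Th and Slc6a3 were lower in KO prefrontal cortex. The mean of Scgn, Slc6a3, Nmb, Nudt8 and Th followed the olfactory bulb score within WT libraries (r = 0.958, p = 0.00033, adjusted p = 6.30e-04; rho = 0.867, p = 0.00225, adjusted p = 0.0045; n = 10; r = 0.719 without the 2 farthest) and within KO libraries (r = 0.923, p = 6.30e-04, adjusted p = 6.30e-04; rho = 0.782, p = 0.0104, adjusted p = 0.0104; n = 10; r = 0.748), which is consistent with more olfactory bulb tissue in the WT samples. Without Nudt8, which shares reads with Doc2g of the score, the values were r = 0.939 (p = 7.50e-04, adjusted p = 7.50e-04; rho = 0.867; r = 0.613 without the 2 farthest) in WT and r = 0.921 (p = 6.80e-04, adjusted p = 7.50e-04; rho = 0.782; r = 0.736) in KO. At an equal score Th differed by -0.30 ± 0.16 (SE), within 2 SE of 0, where it had differed by -1.58 ± 0.36. Scgn differed by -0.57 ± 0.22, Slc6a3 by -2.18 ± 1.01 and Trh by -0.48 ± 0.18. Unlike Th, these 3 stayed beyond 2 SE of 0, though none passed over all genes (edgeR adjusted p = 0.934, 0.953 and 0.910). The Slc6a3 value includes WT replicate 5, at 8.74 CPM where the other WT libraries had 0.0992 to 1.08. Leaving it out moved the difference without the score from -2.99 to -1.70, and the fit with the score was not repeated without it. For these 3 genes a difference in expression cannot be told from a difference in tissue.

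The combined comparison called 650 genes, against 187 with the animal as a random effect and 27 on summed counts. Of 99 splits of the animals that mixed the genotypes, 18 called over 100 genes, as happens when libraries of 1 animal count as independent samples. As many as 650 were called in 10 of 100 splits, the real one included, and the highest other split called 3118, so chance cannot be excluded and the count points to structure among the animals. Off chromosome 5 it was 539 genes, with 11 of 100 splits as large (highest other 2897). On summed counts 3 of 100 splits reached 27 (highest other 117) and 3 of 100 reached the 4 genes off chromosome 5 (highest other 112).

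The other splits gave these values. In hippocampus 2 of 100 reached 20 genes (highest other 150), in prefrontal cortex 2 reached 18 (highest other 3018) and in striatum 4 reached 8 (highest other 1627), the real split included. Each is under the limit of 5 in 100 set beforehand, which was not adjusted over the tests. The real counts also hold Adgrl3, the altered gene itself, so chance cannot be called excluded for the other calls. Splits that call many times the real count point to structure among the samples. The 6 genes called in each region were reached in 1 of 100 (highest other 0). For the interaction 6 of 100 splits reached 4 genes (highest other 119), so chance cannot be excluded. For the region contrasts 1 of 100 reached the real count in each: 1681 for striatum against hippocampus (highest other 622), 2021 for striatum against prefrontal cortex (375) and 1684 for hippocampus against prefrontal cortex (514).

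Single libraries that lay apart from the other 9 of their group were sought in 236 groups by the gap to the nearest value over the range. Chance alone gives about 1 in 20 groups, 11.8 here, and 36 were seen: 19 in WT replicate 5, 9 in KO replicate 7 and 8 elsewhere. In WT replicate 5 of the hippocampus the gap was 0.827 for Cox18, 0.779 for Ssh1, 0.862 for Stbd1, 0.522 for Gcn1l1, 0.564 for Naaa, 0.496 for Paqr3, 0.555 for Rplp0, 0.6002 for Coro1c and 0.532 for Idua. In its prefrontal cortex it was 0.545 for Scarb2, 0.850 for Stbd1, 0.675 for Gcn1l1, 0.628 for Idua, 0.532 for Sdad1, 0.483 for Rplp0, 0.886 for Slc6a3 and 0.540 for Adra1d, and in its striatum 0.797 for Stbd1 and 0.486 for Gcn1l1. In KO replicate 7 of prefrontal cortex it was 0.534 for Scgn, 0.541 for Calb2, 0.577 for Th, 0.570 for Trh, 0.613 for Tbx21, 0.749 for Sp8, 0.6001 for Doc2g, 0.520 for Nmb and 0.601 for Nudt8. Elsewhere it was 0.516 for Anxa3 (KO replicate 8, hippocampus), 0.575 for Nudt8 (WT replicate 7, hippocampus), 0.485 for Cdkl2 (KO replicate 10, prefrontal cortex), 0.516 for Coro1c (KO replicate 8, prefrontal cortex), 0.586 for Npy (WT replicate 6, prefrontal cortex), 0.528 for Adra1b (WT replicate 8, prefrontal cortex), 0.574 for Slc6a3 (WT replicate 7, striatum) and 0.884 for Slc6a3 (KO replicate 10, striatum).

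The genotype difference varied between regions for Scgn (adjusted p = 0.0235), Slc6a3 (0.0472), Nmb (0.0472) and Nudt8 (0.0472) in the edgeR interaction test. These calls did not hold: 0 genes passed with the animal as a block and 0 with the olfactory bulb score as a covariate.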

How the results depend on the processing

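Chosen only after the results were seen were the olfactory bulb score as a covariate, the whole of chromosome 5 as a window, the summed counts without WT replicate 5, the list tests on summed counts, Stbd1 and the interaction genes without the library that lay apart and, for the interaction, leaving out each animal. Counts of calls moved by over 1.5 times as follows. Hippocampus (20): 47 by DESeq2 and 5 with the replicate block (KO n set against WT n). Prefrontal cortex (18): 214 by DESeq2, 55 by voom with quality weights, 4 with surrogate variables, 6 with the olfactory bulb score, 208 in the fit of all 60 libraries and 10 with the replicate block. Striatum (8): 25 by DESeq2, 17 with surrogate variables, 22 in the fit of all 60 libraries and 3 with the replicate block. Combined (650): 364 with the score, and with the animal as replicate block 187 as a random effect and 27 on summed counts (32 without WT replicate 5). Interaction (4): 17 by DESeq2, 1 with RLE size factors, 1 without a filter, 0 with the score (353 genes at an unadjusted p under 0.05 in edgeR) and 0 with the replicate block (1092). Equal numbers do not pair the genotypes: KO n correlated with WT n at a median of -0.14, -0.03 and -0.09 in the 3 regions, and 0, 2 and 0 of 10 correlated best with their own number, so the replicate block within a region is not a paired design. Beyond these counts, the genes given with them in the results and the 3 lists called on summed counts alone (11 in all), no other change of a call with the blocked value is described here. Camera lists went from 6, 10, 12 and 8 in the 3 regions and the combined comparison to 0, 0, 0 and 0 with an estimated correlation and to 0, 4, 0 and 1 by fry, and the combined lists to 4 with the score, whose genes the olfactory bulb list holds. The test near Adgrl3 gave p = 1 at 5 Mb in prefrontal cortex and p = 1 in striatum, with an odds ratio of 0 in both, and in prefrontal cortex p = 1.04e-12 at 20 Mb and 2.61e-13 over chromosome 5. Cdkn1a turned direction with surrogate variables, from 0.29 to -0.0275 (adjusted p = 0.723, edgeR), and it had not passed over all genes.

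Leaving out 1 animal at a time left Adgrl3 between -1.87 and -1.83 in hippocampus, -2.13 and -2.01 in prefrontal cortex, -1.98 and -1.93 in striatum and -1.99 and -1.92 combined. Hippocampus calls ran from 12 to 26 (12 without WT6, WT9, WT10, KO9 or KO10, 13 without KO3). Prefrontal cortex calls ran from 9 to 68 (9 without WT1, WT3, WT9, WT10, KO3 or KO9, 10 without WT8 or KO6, 11 without KO4 or KO10, 40 without WT7 or KO5, 51 without KO1, 68 without KO7). Striatum calls ran from 5 to 15 (5 without WT1, WT2, WT3, WT4, WT10, KO3 or KO9, 15 without WT5). Combined calls ran from 308 to 1133 (308 without KO8, 392 without KO9, 399 without KO10, 1076 without KO1, 1133 without KO5). Interaction calls ran from 0 to 23 (0 without WT1, WT2, WT3, WT9, KO2, KO3, KO5, KO6, KO8, KO9 or KO10, 1 without WT6, 2 without WT8 or WT10, 8 without WT4, 11 without WT7, 23 without KO7). The cause was not tested. A fit with Xist as a covariate was not run, as Xist is not among the genes of the table used here. At this depth edgeR recovered 47.6% of simulated changes of 0.3 in striatum, so smaller changes of a single region can go uncalled.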

Other observations

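The tests in this part were planned, and the genes and lists named in it were chosen only after the results were seen.

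On counts summed per animal further chromosome 5 genes differed between KO and WT. Pde6b, which encodes a photoreceptor phosphodiesterase subunit, fell by 1.19 ± 0.23 (SE, n = 10 animals each, edgeR adjusted p = 0.0255), Shroom3 fell by 0.52 ± 0.09 (0.0114), Ccdc62 fell by 0.44 ± 0.09 (0.0497) and the mitochondrial ribosome gene Mrpl1 fell by 0.12 ± 0.03 (0.0497). Mvk, an enzyme gene of isoprenoid synthesis, rose by 0.13 ± 0.03 (0.0329) and Mthfd2l rose by 0.21 ± 0.04 (0.00967).

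Between regions, dopamine genes were higher in striatum in 16 of 21 measured against hippocampus (median log2 difference 2.28) and in 16 of 21 against prefrontal cortex (1.98). Ependymal markers were higher in hippocampus than in prefrontal cortex in 12 of 12 (median 2.59). Microglia markers were higher in striatum than in hippocampus in 14 of 14 (median 0.28), and excitatory neuron markers were lower in striatum than in prefrontal cortex in 14 of 17 (median -1.37).

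The Y chromosome genes Ddx3y, Eif2s3y, Uty and Kdm5d had at least 2194, 448, 405 and 587 reads in each of the 60 libraries, so each library held male tissue. Pmch reached a mean of 3.12 ± 10.7 CPM over the 30 KO libraries against 0.19 ± 0.11 in WT, an SD above the mean.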
